A study of Homo sapiens with 11 samples.

How the data were processed

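PAT-seq libraries were made from 1 µg of total RNA and sequenced as single reads of 150 bases, per the labels. The submitters' processing notes name STAR for alignment without a version. The genome build, the gene annotation, the counting rule and its use of strand are not given in the sources used here. Start and end coordinates were identical to those of GENCODE 29 (GRCh38) for 56532 of the 57345 genes found there, out of 57593 in the tables, and 134 entries joined several gene IDs. The deposited tables give, for each gene and library, the raw count of reads, the count of reads in which a poly(A) tail was seen and the mean tail length. None of these counts had been normalised, as checked on the values, which were whole numbers. The deposited tail lengths ran from 4 to 131, and bases were inferred as their unit from the read length. The tables hold no separate 3′ ends within a gene, so poly(A) site usage was not analysed here. Because strand use is not known, reads of overlapping or antisense genes cannot be told apart, nor can those of near-identical copies such as histone and ribosomal protein genes.

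Libraries were grouped by title: MCF7 (n = 2), MDAMB231 (n = 2), siNT (n = 3), siPCF11 (n = 2) and siCLP1 (n = 2). Cells were seeded at 250000 (MCF7) or 100000 (MDAMB231) per well. Per the labels, siNT wells received 6 µl of a 5 µM siRNA stock and knockdown wells 15 µl of each of 2 stocks, in 250 µl. The labels do not say which CLP1 siRNAs were combined, and the letters M and L in the titles are not explained. Same-numbered siNT and siPCF11 libraries also share a title letter, but the labels do not say that a number or a letter marks a batch, so no block was used in the planned fits. The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. MDAMB231 was compared with MCF7 in a fit of 4 libraries, and siPCF11 and siCLP1 with siNT and with each other in a fit of 7 libraries. Depth ran from 5082772 to 15561054 reads per library.

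Gene counts were filtered with filterByExpr, normalised with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Tail lengths were tested with limma 3.58.1 (trend and robust) over genes with at least 20 tail-bearing reads in every library of the fit. A second limma test weighted each value by its tail-bearing reads and was added after the data were seen. The 17 gene lists, of which 407 of 430 symbols were in the tables, were tested with camera of limma on voom values. Camera used a preset correlation of 0.01 between genes, with an estimated correlation beside it. Fry tested whether a list's genes move one way on balance and compares a list with no other genes. PCF11 and CLP1 stayed out of the lists in the knockdown comparisons. Named genes were the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups, and up to 4 members per list by adjusted p. Members that moved against their list, VIM, SPARC and the genes of the weighted tail tests were chosen after their values were seen. For tails, 4 genes per direction were named, and for the overlap 6 genes. Folds against a group without reads are lower bounds from 3 counts over that group, and list medians were the same with such genes at their bounds. Intervals of single libraries are 95% exact Poisson intervals. The overlap of the knockdowns was set beside 20 simulations of unchanged groups that shared the siNT libraries.

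The steps were tested on simulated data. With 4 libraries of 16075 genes, 46.3% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 92.4% of those changed 4-fold were called. With 7 libraries of 14429 genes these shares were 8.96%, 46.3% and 80.3%. A tail shift of 15 bases was called in 79% and 88% of genes unweighted, and in 85% and 90.5% weighted. Of the unchanged genes, 7 and 16 were called unweighted, and 3 and 10 weighted. The simulated tails had the same assumed spread in every gene, so these shares can overstate what the tests find in real data. The alternatives were DESeq2 1.42.0 size factors, the DESeq2 test, no low-count filter, a test against a 2-fold change (glmTreat), all 11 libraries in a fit, replicate number or title letter as a block, and leaving out each library. For tails they were minimums of 10 and 50 reads, centring on library medians and a log scale. Tail-bearing reads alone, and the weighted tail test with its own alternatives, were added after the data were seen.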

Results

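PAT-seq, which sequences the 3′ ends of polyadenylated RNA together with the start of the poly(A) tail, was applied to total RNA of 2 human breast cancer cell lines. MCF7 is an estrogen-responsive line with luminal epithelial features, and MDA-MB-231 (MDAMB231 in the group names) is a line with mesenchymal features. The libraries formed 5 groups: untransfected MCF7 (n = 2) and MDAMB231 (n = 2), and MCF7 cells transfected with a non-targeting siRNA (siNT, n = 3), with siRNAs against PCF11 (siPCF11, n = 2) or with siRNAs against CLP1 (siCLP1, n = 2). PCF11 and CLP1 are the subunits of cleavage factor II, which acts in pre-mRNA 3′ end cleavage and in transcription termination. Reads assigned to genes came to 13076839 and 15561054 in MCF7, 10991519 and 12952573 in MDAMB231, 5082772 to 10311132 in siNT, 5280039 and 7332789 in siPCF11 and 5528541 and 11861215 in siCLP1. A poly(A) tail was seen in 57.5% ± 0.438 (SD) of reads in MCF7, 57.3% ± 0.654 in MDAMB231, 64.9% ± 1.90 in siNT, 61.4% ± 2.78 in siPCF11 and 68.3% ± 0.460 in siCLP1. Mitochondrial transcripts took 25.6% ± 0.144 and 25.6% ± 0.273 of reads in the cell lines, 25.3% ± 1.00 in siNT, 20.7% ± 2.28 in siPCF11 and 23.1% ± 2.14 in siCLP1. Unless stated otherwise, values are mean ± SD over the libraries of a group in counts scaled to library size (CPM), with the n given here, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which can be technical.

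The transcripts targeted by the siRNAs were examined first. PCF11 (ENSG00000165494, chromosome 11, 83156988 to 83187451, plus strand) stood at 20.9 ± 2.45 CPM in siNT and 11.6 ± 0.107 CPM in siPCF11, and it fell 1.81-fold (log2 fold change -0.86, SE 0.24, edgeR adjusted p = 0.0131). Its levels in the siPCF11 libraries were 11.5 (95% interval 9.07 to 14.4) and 11.6 (95% interval 8.90 to 14.95) CPM, below 18.4 (95% interval 15.8 to 21.3), 21.2 (95% interval 17.5 to 25.5) and 23.3 (95% interval 20.3 to 26.6) CPM in siNT. This call missed the threshold without siNT replicate 5 (edgeR adjusted p = 0.0668), siPCF11 replicate 3 (0.0881) or siPCF11 replicate 4 (0.0907), and the fold change kept its sign. CLP1 (ENSG00000172409, chromosome 11, 57648992 to 57661868, plus strand) was a low transcript, at 6.57 (95% interval 5.06 to 8.39), 6.00 (95% interval 4.10 to 8.47) and 7.65 (95% interval 5.98 to 9.63) CPM in siNT. In the libraries labelled CLP1 knockdown it stood at 4.15 (95% interval 3.07 to 5.48) and 6.92 (95% interval 4.95 to 9.43) CPM. A lower CLP1 mRNA was therefore not shown in these libraries (log2 fold change -0.33, SE 0.32, 95% interval -0.99 to 0.33, edgeR adjusted p = 0.516), and each siCLP1 result is that of libraries so labelled. Counted over tail-bearing reads alone, the log2 fold change of CLP1 was 0.091 (edgeR adjusted p = 0.9), and without siCLP1 replicate 1 it was 0.031 (edgeR adjusted p = 0.977), so its direction was not settled. A tail was seen in 42 of 49 and 40 of 40 CLP1 reads in siCLP1, against 47 of 64, 23 of 32 and 47 of 72 in siNT. Mean CLP1 tails were 91.0 and 83.8 bases in siCLP1, 45.0, 47.1 and 67.7 bases in siNT, and 56.2 and 69.8 bases in siPCF11. This was not tested, since siPCF11 replicate 4 held 16 tail-bearing reads of CLP1. The sample characteristics write CLIP1 where the titles write CLP1. CLIP1, a microtubule plus-end protein, stood at 57.4 ± 25.8 against 74.3 ± 14.6 CPM in siCLP1 and siNT and did not pass the test either (log2 fold change -0.36, edgeR adjusted p = 0.34, and 0.022 without siCLP1 replicate 3). PCF11 rose in the siCLP1 libraries (35.6 ± 10.3 against 20.9 ± 2.45 CPM, log2 fold change 0.76, edgeR adjusted p = 0.0184), a call that was lost without siNT replicate 3 (adjusted p = 0.0649), siNT replicate 4 (0.0536) or siCLP1 replicate 3 (0.246). CLP1 did not pass the test in siPCF11 (9.02 ± 1.16 against 6.74 ± 0.837 CPM, log2 fold change 0.42, edgeR adjusted p = 0.366). Intervals cover counting error only, since reads are not independent molecules.

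**Figure D1:**
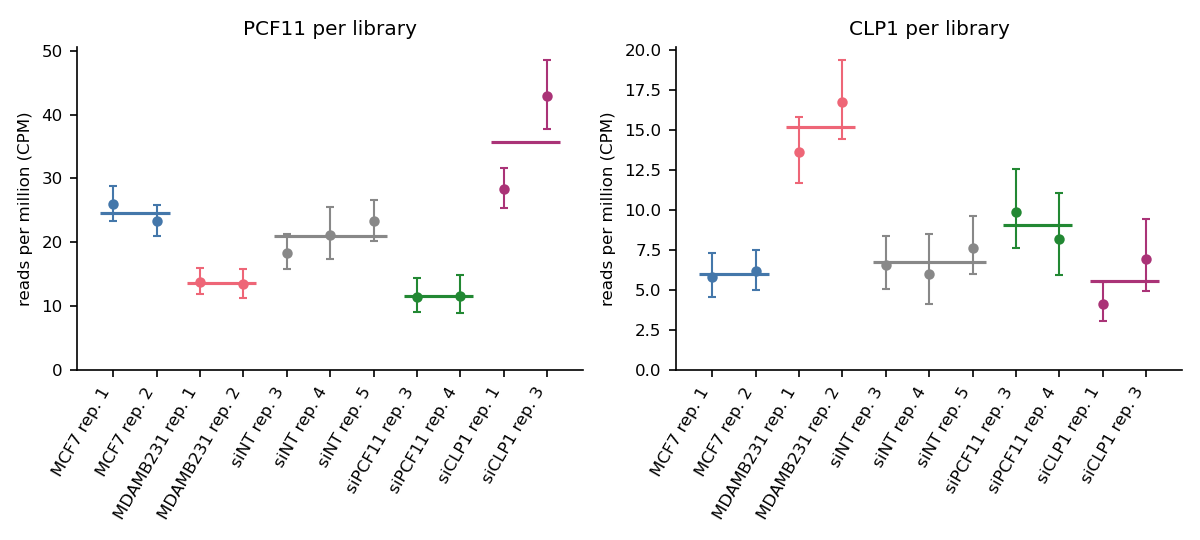
Level in CPM of PCF11 (left) and CLP1 (right) in each of the 11 libraries, coloured by group, with 95% Poisson intervals of the read count and group means as horizontal lines. PCF11 stands at 11.5 and 11.6 CPM in siPCF11 and 18.4 to 23.3 CPM in siNT, and of the CLP1 values in siCLP1, 4.15 CPM lies below and 6.92 CPM within the siNT range of 6.00 to 7.65 CPM.

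The comparison of the cell lines asked how 3′ end expression differed between MDAMB231 and MCF7. In MDAMB231, 29 of 30 luminal epithelial markers and 23 of 26 estrogen response genes fell, and 25 of 26 mesenchymal markers rose. Most mitotic and DNA replication genes rose as well, while most histone, p53 target and cholesterol synthesis genes fell. Of 16075 genes tested, 12083 changed, 5813 higher and 6270 lower in MDAMB231, and 7862 of these differed at least 2-fold. Among luminal epithelial markers, 1 of 30 tested members rose and 29 fell (1 and 29 adjusted over the list alone), with a median log2 fold change of -6.51 (limma camera adjusted p = 1.56e-12, adjusted p = 0.238 with an estimated correlation). TFF1, a secreted trefoil peptide induced by estrogen, stood at 8.62 ± 1.85 against 6612 ± 120.1 CPM in MDAMB231 and MCF7 (log2 fold change -9.60, SE 0.11, edgeR adjusted p = 5.7e-51). KRT19, a keratin of simple epithelia, stood at 15.3 ± 1.56 against 2838 ± 107 CPM, AGR2, an endoplasmic reticulum disulfide isomerase, at 1.57 ± 0.396 against 487 ± 14.2 CPM, and TFF3, another trefoil peptide, at 0.599 ± 0.194 against 383 ± 4.07 CPM. The luminal marker that rose was KRT7 (log2 fold change 2.82, edgeR adjusted p = 6.91e-23). ESR1 was not analysed here. Of the estrogen response genes, 3 of 26 tested members rose and 23 fell (3 and 23 adjusted over the list alone, limma camera adjusted p = 7.66e-08, adjusted p = 0.238 with an estimated correlation). These included AREG, a ligand of the EGF receptor (8.52 ± 0.952 against 421 ± 39.6 CPM), and GREB1, an early estrogen-induced gene (0.745 ± 0.143 against 171 ± 9.37 CPM). Those that rose were IGFBP4, SLC7A5 and MYBL1.

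Mesenchymal genes went the other way: 25 of 26 tested members rose and 0 fell (25 and 0 adjusted over the list alone), with a median log2 fold change of 3.92 (limma camera adjusted p = 2.04e-11, adjusted p = 0.289 with an estimated correlation). LGALS1, which encodes a secreted galectin, stood at 2526 ± 135 against 248 ± 2.93 CPM, and NT5E, a cell surface nucleotidase, at 515 ± 17.6 against 41.3 ± 0.736 CPM. PLAUR, the urokinase receptor, rose 37.6-fold and ANXA1, a phospholipid-binding annexin, 13.3-fold. VIM, the intermediate filament of mesenchymal cells, was at 2208 and 2007 CPM in MDAMB231, and at 16.2 CPM in MCF7 replicate 1 and 44.6 CPM in MCF7 replicate 2. SPARC was the tested member that did not pass. Over 41 genes above 50 CPM in MDAMB231 and under 0.2% of that level in siNT, the median level was 1.09% of MDAMB231 in MCF7 replicate 2 and 0.282% in MCF7 replicate 1. Without MCF7 replicate 2, 11400 genes were called between the lines. Among markers of stromal, endothelial and blood cells, 1 rose and 3 fell of 5 (1 and 3 adjusted over the list alone, limma camera adjusted p = 0.612, adjusted p = 0.702 with an estimated correlation). These were PECAM1, an endothelial adhesion molecule with no reads in MCF7 (at least 9.53-fold higher), and the lower HBA1 (0.130 ± 0.0756 against 12.3 ± 0.846 CPM), COL3A1 (0.138 ± 0.195 against 2.33 ± 0.154 CPM) and COL1A1 (5.99 ± 1.94 against 10.2 ± 2.68 CPM), an alpha-globin and fibrillar collagens.

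**Figure D2:**
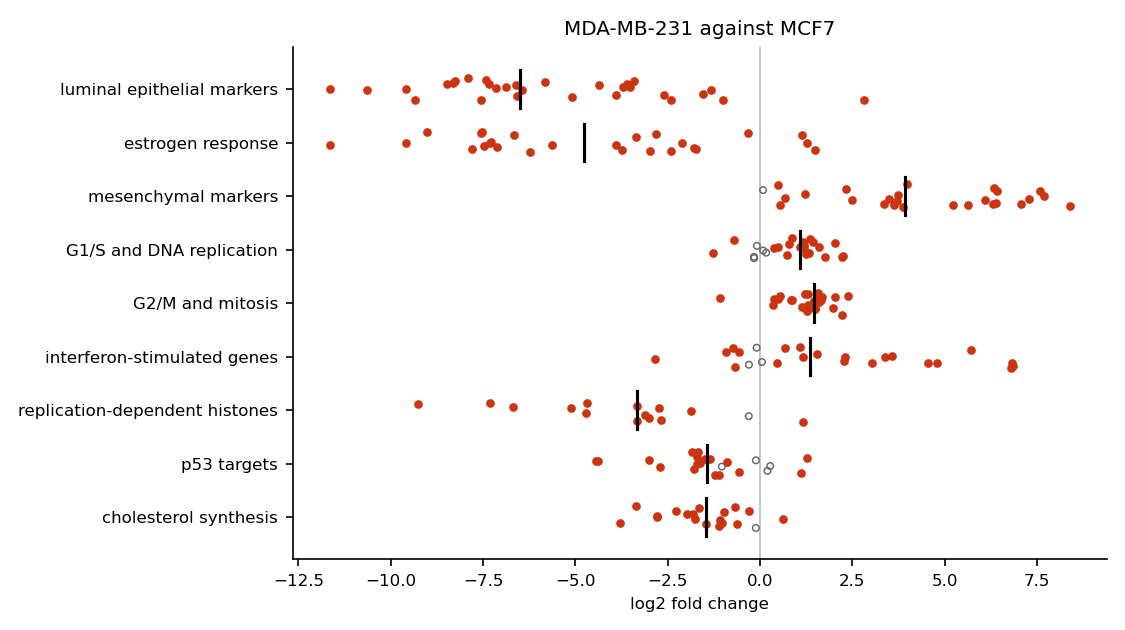
Log2 fold change of each tested gene of 9 lists between MDAMB231 and MCF7, positive where MDAMB231 was higher. Filled points passed the edgeR test (adjusted p under 0.05), open points did not, vertical spread within a list is random, and black bars are list medians, which run from -6.51 for luminal epithelial markers to 3.92 for mesenchymal markers.

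Genes of the cell cycle were higher in MDAMB231. In the G2/M and mitosis list, 24 of 25 tested members rose and 1 fell (24 and 1 adjusted over the list alone, limma camera adjusted p = 4.39e-08, adjusted p = 0.238 with an estimated correlation). Among these were CDC20, an activator of the anaphase-promoting complex (454 ± 0.924 against 87.5 ± 5.19 CPM), the kinetochore protein CENPF (108 ± 2.15 against 23.1 ± 0.459 CPM) and the kinase AURKB (122 ± 3.33 against 29.9 ± 0.717 CPM). HMMR was the member that fell. In the G1/S and DNA replication list, 18 of 25 tested members rose and 2 fell (18 and 2 adjusted over the list alone, limma camera adjusted p = 0.000233, adjusted p = 0.315 with an estimated correlation). RRM1, the large subunit of ribonucleotide reductase, rose 4.73-fold and the origin licensing factor CDC6 4.68-fold, whereas GINS2 and E2F2 fell. Replication-dependent histone genes, whose main transcripts end without a poly(A) tail, were lower: 1 of 15 tested members rose and 13 fell (1 and 13 adjusted over the list alone, limma camera adjusted p = 4.21e-05, adjusted p = 0.238 with an estimated correlation). HIST2H2AA3 stood at 2.77 ± 0.540 against 72.1 ± 5.83 CPM and HIST2H2BE at 1.47 ± 0.126 against 51.3 ± 0.418 CPM, and HIST1H2BK was the member that rose. Of the p53 targets, 2 of 22 tested members rose and 16 fell (2 and 16 adjusted over the list alone, limma camera adjusted p = 0.00265, adjusted p = 0.289 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, stood at 16.3 ± 0.918 against 131 ± 3.97 CPM and the pro-apoptotic BBC3 at 5.19 ± 0.711 against 34.5 ± 3.95 CPM, and TNFRSF10B and PLK3 rose. Of the cholesterol synthesis genes, 1 of 19 tested members rose and 17 fell (1 and 17 adjusted over the list alone, limma camera adjusted p = 1.01e-05, adjusted p = 0.238 with an estimated correlation). The epoxidase SQLE fell 13.8-fold and the reductase DHCR7 10.3-fold, and LDLR, the LDL receptor, was the member that rose. Of the interferon-stimulated genes, 16 of 24 tested members rose and 5 fell (16 and 5 adjusted over the list alone, limma camera adjusted p = 0.00989, adjusted p = 0.315 with an estimated correlation). Among these were IFIT3 (51.6 ± 2.27 against 0.448 ± 0.0923 CPM) and the transcription factor IRF1 (37.1 ± 0.867 against 4.46 ± 1.32 CPM).

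Other lists held genes that moved in both directions. Of the cleavage and polyadenylation factors, 12 rose and 9 fell of 28 (12 and 9 adjusted over the list alone, limma camera adjusted p = 0.612, adjusted p = 0.702 with an estimated correlation). CLP1 rose 2.52-fold (15.2 ± 2.20 against 5.99 ± 0.241 CPM, log2 fold change 1.33, edgeR adjusted p = 3.26e-08). PCF11 fell 1.81-fold (13.6 ± 0.247 against 24.6 ± 1.88 CPM, log2 fold change -0.85, edgeR adjusted p = 8.1e-07). NUDT21, a subunit of cleavage factor I, stood at 98.0 ± 0.641 against 55.2 ± 0.529 CPM and PABPC4, a cytoplasmic poly(A)-binding protein, at 192 ± 0.915 against 75.4 ± 0.702 CPM. Of the tRNA splicing endonuclease and ligase subunits, 5 rose and 1 fell of 9 (4 and 1 adjusted over the list alone, limma camera adjusted p = 0.32, adjusted p = 0.702 with an estimated correlation). TSEN15 stood at 93.9 ± 0.715 against 50.03 ± 1.15 CPM and TSEN54 at 32.2 ± 3.46 against 63.9 ± 10.2 CPM. Of the integrated stress and unfolded protein response genes, 10 rose and 6 fell of 20 (10 and 7 adjusted over the list alone, limma camera adjusted p = 0.32, adjusted p = 0.581 with an estimated correlation). SLC7A11, a cystine transporter, rose 91.0-fold, and PHGDH, the first enzyme of serine synthesis, fell 18.6-fold. Of the cytosolic ribosomal protein genes, 32 rose and 29 fell of 78 (32 and 29 adjusted over the list alone, limma camera adjusted p = 0.642, adjusted p = 0.808 with an estimated correlation). Of the mitochondrially encoded mRNAs, 5 rose and 7 fell of 13 (5 and 7 adjusted over the list alone, limma camera adjusted p = 0.612, adjusted p = 0.808 with an estimated correlation). MT-ND6 stood at 1272 ± 2.41 against 411 ± 39.1 CPM and MT-CYB at 8731 ± 434 against 19449 ± 954 CPM. Of the immediate early genes, 7 rose and 7 fell of 17 (7 and 7 adjusted over the list alone, limma camera adjusted p = 0.981, adjusted p = 0.982 with an estimated correlation). FOS stood at 0.668 ± 0.0346 against 37.4 ± 2.16 CPM and IER3 at 155 ± 3.57 against 55.3 ± 0.466 CPM. Their median of -0.023 and mean of -0.41 were negative while camera's direction was up. Of the genes often studied for 3′ end choice, 9 rose and 8 fell of 20 (9 and 8 adjusted over the list alone, limma camera adjusted p = 0.761, adjusted p = 0.808 with an estimated correlation). The metalloproteinase inhibitor TIMP2 stood at 157 ± 0.660 against 27.1 ± 1.55 CPM and CD47 at 27.6 ± 1.93 against 81.6 ± 3.80 CPM.

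Among genes of at least 10 CPM, the largest rises had no reads in MCF7: CST7, which encodes a cystatin (39.7 ± 2.31 CPM in MDAMB231, at least 379-fold higher), AC244153.1 (at least 270.1-fold), the caveolar coat protein CAVIN2 (at least 233-fold), SH3RF3 (at least 203-fold), KCTD14 (at least 179-fold), the collagen COL8A1 (at least 161-fold), CDK15 (at least 152-fold) and LINC02577 (at least 141-fold). The largest falls had no reads in MDAMB231: the transcription factor SOX3 (60.5 ± 1.11 CPM in MCF7, at least 481-fold lower), the sphingolipid desaturase DEGS2 (at least 385-fold), the serine protease KLK11 (at least 296-fold), PRR15L (at least 276-fold), the Rho inhibitor ARHGDIG (at least 262-fold), the potassium channel KCNK15 (at least 252-fold), the 7SL pseudogene RN7SL674P (at least 249.8-fold) and the complement receptor C5AR2 (at least 249-fold). Bounds use 3 reads over the group without reads, and reads of RN7SL674P can belong to near-identical copies. With 2 libraries per line, 6227 genes passed a test against a 2-fold change. The lines also differed in growth medium and seeding density, so line and culture cannot be separated. For the 9 lists called here, limma's fry test of whether a list moved one way on balance gave adjusted p from 0.000207 to 0.0088. Unlike camera, fry also called cleavage and polyadenylation factors (limma fry adjusted p = 0.0283) and tRNA splicing subunits (0.0291) upwards. It called integrated stress and unfolded protein response genes upwards too (0.0146), and mitochondrially encoded mRNAs downwards (0.0329).

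The next comparison asked which genes changed after depletion of PCF11 in MCF7 cells. In the lists of DNA replication, mitosis, estrogen response, ribosomal protein and 3′ end processing genes (PCF11 left out), members rose and none fell, and 10 of 15 replication-dependent histone genes fell. Of 14429 genes tested, 3001 changed, 1424 higher and 1577 lower, and 1595 of them at least 2-fold (634 higher, 961 lower). The counts are reads per gene in both knockdowns. Without separate 3′ ends, a change in mRNA amount cannot be told from 3′ ends moving into or out of the annotated gene. Among the strongest rises, ADM5, of the adrenomedullin family, stood at 64.4 ± 4.51 against 5.11 ± 1.37 CPM in siPCF11 and siNT (log2 fold change 3.63, SE 0.22, edgeR adjusted p = 3.92e-09). The Nudix hydrolase NUDT3 stood at 225 ± 28.7 against 27.4 ± 5.93 CPM, the membrane protein CMTM6 at 45.5 ± 3.96 against 5.57 ± 0.510 CPM and the desaturase TMEM189, whose locus is also read into its neighbour UBE2V1, at 99.4 ± 16.5 against 16.5 ± 3.22 CPM. The other leading rises were the lincRNAs AL023284.4 (log2 fold change 3.54) and AC145207.5 (2.71), the sense intronic AC006538.1 (3.06) and the pseudogene CTBP2P1 (2.89), whose reads can be shared with CTBP2. ST6GAL1, a Golgi sialyltransferase, fell from 17.4 ± 5.77 to 1.64 ± 0.427 CPM (log2 fold change -3.38, SE 0.39, edgeR adjusted p = 5.86e-06). The other leading falls were the galactosyltransferase B3GALT4 (1.91 ± 0.804 against 16.1 ± 2.95 CPM), METTL7B (1.60 ± 0.908 against 14.2 ± 0.688 CPM), the fatty acid hydroxylase CYP4F11 (1.18 ± 0.861 against 10.7 ± 2.64 CPM), and the thiamine triphosphatase THTPA (1.53 ± 0.265 against 12.7 ± 1.57 CPM). They also included the histone gene HIST1H3G (1.19 ± 0.206 against 12.3 ± 2.96 CPM) and the lincRNAs LINC01213 (log2 fold change -3.87) and AC106782.2 (-3.38).

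In the G1/S and DNA replication list, 12 of 25 tested members rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.58 (limma camera adjusted p = 2.08e-06, adjusted p = 0.225 with an estimated correlation). The licensing factor CDT1 stood at 109 ± 8.55 against 50.5 ± 3.89 CPM, the chromatin protein UHRF1 at 22.5 ± 0.337 against 8.47 ± 1.18 CPM and the helicase subunit MCM7 at 247 ± 0.556 against 131 ± 19.98 CPM. In the G2/M and mitosis list, 5 of 25 tested members rose and 0 fell (6 and 0 adjusted over the list alone, limma camera adjusted p = 0.00614, adjusted p = 0.331 with an estimated correlation). Among these were the kinase PLK1 (147 ± 4.14 against 48.3 ± 5.89 CPM) and the inhibitor of apoptosis BIRC5 (180.1 ± 24.8 against 102 ± 13.9 CPM). Of the replication-dependent histone genes, 1 of 15 tested members rose and 10 fell (2 and 10 adjusted over the list alone, limma camera adjusted p = 8.98e-06, adjusted p = 0.234 with an estimated correlation). HIST2H2AA3 stood at 4.35 ± 0.871 against 27.0 ± 2.89 CPM and the linker histone gene HIST1H1C at 9.77 ± 2.22 against 47.0 ± 6.25 CPM, and HIST2H2AC was the member that rose (log2 fold change 0.56). Reads of these near-identical gene copies can be split between them. The main transcripts of these genes end without a poly(A) tail, so the counts need not follow total histone mRNA. Of the cleavage and polyadenylation factors other than PCF11 and CLP1, 6 of 26 tested members rose and 0 fell (6 and 0 adjusted over the list alone, limma camera adjusted p = 0.00521, adjusted p = 0.234 with an estimated correlation). The scaffold SYMPK stood at 38.4 ± 6.65 against 14.6 ± 1.31 CPM, RBBP6 at 419 ± 34.7 against 190.3 ± 22.7 CPM and the nuclear poly(A)-binding protein PABPN1 at 145 ± 6.91 against 84.7 ± 11.7 CPM. Of the estrogen response genes, 5 of 25 tested members rose and 0 fell (6 and 0 adjusted over the list alone, limma camera adjusted p = 0.00179, adjusted p = 0.52 with an estimated correlation). Among these were the carbonic anhydrase CA12 (554 ± 18.9 against 151 ± 15.8 CPM), the transcription factor MYB (19.2 ± 5.46 against 5.41 ± 0.580 CPM) and the retinoic acid receptor RARA (73.1 ± 18.1 against 30.7 ± 6.49 CPM). Of the cytosolic ribosomal protein genes, 12 of 78 tested members rose and 0 fell (9 and 0 adjusted over the list alone, limma camera adjusted p = 4.25e-11, adjusted p = 0.52 with an estimated correlation). RPS12 stood at 1471 ± 178 against 745 ± 185 CPM. Mitochondrial reads made up 20.7% ± 2.28 of these libraries and 25.3% ± 1.00 of siNT. Of the genes often studied for 3′ end choice, 5 of 17 tested members rose and 1 fell (5 and 1 adjusted over the list alone, limma camera adjusted p = 0.0451, adjusted p = 0.52 with an estimated correlation), with the kinases PAK2 (80.3 ± 1.11 against 45.1 ± 3.38 CPM) and PAK1 (10.5 ± 0.0362 against 4.32 ± 1.63 CPM).

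In the planned fit, without a block, camera called no shift for the remaining lists. Of the integrated stress and unfolded protein response genes, 4 rose and 1 fell of 20 (4 and 1 adjusted over the list alone, limma camera adjusted p = 0.0552), and the transcription factor ATF4 stood at 267 ± 3.20 against 64.2 ± 11.3 CPM. Of the interferon-stimulated genes, 0 rose and 4 fell of 19 (0 and 5 adjusted over the list alone, limma camera adjusted p = 0.0643). IRF7 stood at 3.06 ± 1.36 against 14.3 ± 3.51 CPM. Of the p53 targets, 3 rose and 4 fell of 22 (3 and 4 adjusted over the list alone, limma camera adjusted p = 0.907): TP53I3 stood at 8.34 ± 2.35 against 32.2 ± 2.65 CPM and the ubiquitin ligase MDM2 at 105 ± 12.3 against 51.2 ± 7.36 CPM. Of the luminal epithelial markers, 2 rose and 4 fell of 30 (2 and 4 adjusted over the list alone, limma camera adjusted p = 0.973). MUC1, a membrane mucin, stood at 33.2 ± 8.35 against 85.4 ± 22.1 CPM. The median and mean log2 fold changes of these markers were -0.030 and 0.028. Of the mesenchymal markers, 1 rose and 0 fell of 12 (0 and 0 adjusted over the list alone, limma camera adjusted p = 0.367). CAV2 rose (7.33 ± 1.51 against 3.06 ± 0.903 CPM). Of the tRNA splicing subunits, 2 rose and 1 fell of 9 (3 and 1 adjusted over the list alone, limma camera adjusted p = 0.367). TSEN34 stood at 70.7 ± 6.70 against 24.5 ± 3.81 CPM. Of the mitochondrially encoded mRNAs, 0 rose and 1 fell of 13 (0 and 1 adjusted over the list alone, limma camera adjusted p = 0.0519). MT-ATP8 fell (477 ± 34.0 against 971 ± 77.3 CPM). Of the cholesterol synthesis genes, 2 rose and 3 fell of 20 (2 and 3 adjusted over the list alone, limma camera adjusted p = 0.134). SC5D stood at 14.1 ± 4.55 against 35.8 ± 6.01 CPM. Of the immediate early genes, 4 rose and 0 fell of 16 (4 and 0 adjusted over the list alone, limma camera adjusted p = 0.178). SRF stood at 40.9 ± 0.964 against 17.1 ± 1.74 CPM. Of the stromal, endothelial and blood cell markers, 0 rose and 1 fell of 3 (0 and 1 adjusted over the list alone, limma camera adjusted p = 0.367). COL1A1 fell (15.05 ± 0.236 against 31.2 ± 4.32 CPM). The count of 3001 became 1951 without siNT replicate 5, 1877 without siPCF11 replicate 3 and 1431 without siPCF11 replicate 4, and 282 genes passed a test against a 2-fold change. Each knockdown well received 15 µl of each of 2 siRNA stocks and each non-targeting well 6 µl of a stock, so siRNA amount and target cannot be separated. For the 7 lists called here, limma's fry test of whether a list moved one way on balance gave adjusted p from 0.00697 to 0.101. Fry did not call the estrogen response genes (limma fry adjusted p = 0.101) or the cytosolic ribosomal protein genes (0.0947). Nor did it call the genes often studied for 3′ end choice (0.0541).

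The libraries labelled CLP1 knockdown were compared with siNT in the same way. In the lists of DNA replication, mitosis and 3′ end processing genes, members rose and none fell. Of the estrogen response genes 9 rose and 1 fell, and 9 of 15 replication-dependent histone genes fell. Of 14429 genes tested, 2394 changed, 1266 higher and 1128 lower, and 1163 of them at least 2-fold (626 higher, 537 lower). CMTM6 stood at 43.5 ± 10.6 against 5.57 ± 0.510 CPM in siCLP1 and siNT (log2 fold change 2.96, SE 0.21, edgeR adjusted p = 3.19e-08) and NUDT3 at 189 ± 37.8 against 27.4 ± 5.93 CPM. The acyl-CoA ligase ACSL4 stood at 10.5 ± 0.526 against 1.49 ± 0.343 CPM, the vesicle membrane protein SCAMP2 at 84.0 ± 8.87 against 13.3 ± 1.74 CPM, the RNA-binding protein RAVER1 at 187 ± 35.3 against 29.6 ± 8.35 CPM and the cell cycle kinase CDK2 at 33.7 ± 3.55 against 5.29 ± 0.897 CPM. The other leading rises were AC069499.1 (log2 fold change 2.84) and LINC01963 (2.70). ST6GAL1 fell from 17.4 ± 5.77 to 0.725 ± 0.291 CPM (log2 fold change -4.46, SE 0.42, edgeR adjusted p = 1.03e-06). VTCN1, an inhibitory ligand of T cells, stood at 0.942 ± 0.136 against 13.2 ± 2.02 CPM, the proprotein convertase FURIN at 1.40 ± 1.01 against 11.1 ± 1.90 CPM, the metalloproteinase inhibitor TIMP3 at 2.23 ± 1.24 against 12.8 ± 5.75 CPM and the kinesin KIF5C at 2.56 ± 1.17 against 16.3 ± 4.86 CPM. The cytokine GDF15, also among the p53 targets, stood at 17.4 ± 0.881 against 74.4 ± 17.6 CPM, the inhibin subunit INHA at 4.91 ± 1.56 against 21.4 ± 8.27 CPM and SMIM5 at 2.18 ± 0.0942 against 11.0 ± 1.41 CPM.

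In the G1/S and DNA replication list, 13 of 25 tested members rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.60 (limma camera adjusted p = 8.99e-08, adjusted p = 0.137 with an estimated correlation). UHRF1 stood at 30.3 ± 2.74 against 8.47 ± 1.18 CPM and MCM2 at 70.8 ± 2.48 against 32.6 ± 4.34 CPM. In the G2/M and mitosis list, 9 of 25 tested members rose and 0 fell (10 and 0 adjusted over the list alone, limma camera adjusted p = 0.00011, adjusted p = 0.243 with an estimated correlation). Among these were PLK1 (122 ± 19.6 against 48.3 ± 5.89 CPM) and the checkpoint kinase BUB1B (10.3 ± 2.02 against 3.56 ± 1.09 CPM). Of the estrogen response genes, 9 of 25 tested members rose and 1 fell (13 and 1 adjusted over the list alone, limma camera adjusted p = 9.42e-05, adjusted p = 0.487 with an estimated correlation). CA12 stood at 611 ± 0.00723 against 151 ± 15.8 CPM and IGFBP4, an insulin-like growth factor binding protein, at 241 ± 53.3 against 86.5 ± 5.69 CPM, and CCND1, which encodes cyclin D1, was the member that fell (173 ± 17.2 against 372 ± 31.6 CPM). Of the replication-dependent histone genes, 1 of 15 tested members rose and 9 fell (1 and 9 adjusted over the list alone, limma camera adjusted p = 0.00011, adjusted p = 0.243 with an estimated correlation). HIST1H2AC stood at 21.8 ± 4.39 against 65.6 ± 11.5 CPM and HIST1H2BC at 5.78 ± 0.0923 against 21.9 ± 2.89 CPM. HIST1H4C was the member that rose (log2 fold change 1.94). As after siPCF11, counts of these genes need not follow total histone mRNA. Of the cleavage and polyadenylation factors other than PCF11 and CLP1, 5 of 26 tested members rose and 0 fell (5 and 0 adjusted over the list alone, limma camera adjusted p = 0.0236, adjusted p = 0.265 with an estimated correlation). Among these were SYMPK (30.04 ± 0.585 against 14.6 ± 1.31 CPM) and RBBP6 (348 ± 55.2 against 190.3 ± 22.7 CPM). The share of mitochondrial reads was 23.1% ± 2.14 here and 25.3% ± 1.00 in siNT.

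**Figure D3:**
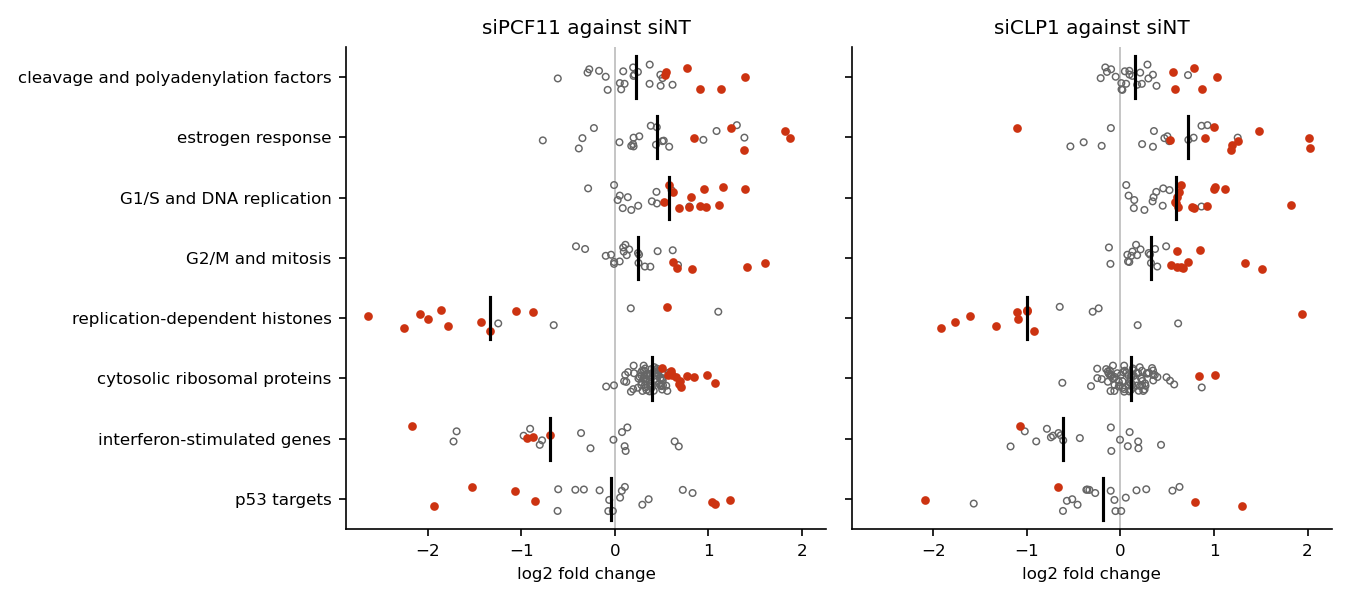
Log2 fold change against siNT of each tested gene of 8 lists after siPCF11 (left) and siCLP1 (right). Filled points passed the edgeR test (adjusted p under 0.05), open points did not, vertical spread within a list is random, and black bars are list medians; the median of the replication-dependent histones is -1.33 on the left and -0.997 on the right.

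Camera called no shift for the other lists in siCLP1. Of the p53 targets, 2 rose and 2 fell of 22 (2 and 2 adjusted over the list alone, limma camera adjusted p = 0.354). CCNG1, a cyclin G gene, stood at 75.4 ± 19.1 against 30.7 ± 4.46 CPM. Of the luminal epithelial markers, 4 rose and 1 fell of 30 (4 and 1 adjusted over the list alone, limma camera adjusted p = 0.87). The zinc transporter SLC39A6 stood at 81.2 ± 9.73 against 180.3 ± 21.4 CPM. These markers had a median log2 fold change of -0.010 and a mean of 0.11. Of the mesenchymal markers, 0 rose and 1 fell of 12 (0 and 0 adjusted over the list alone, limma camera adjusted p = 0.713). EGFR fell (0.256 ± 0.117 against 1.65 ± 0.880 CPM). Of the interferon-stimulated genes, 0 rose and 1 fell of 19 (0 and 1 adjusted over the list alone, limma camera adjusted p = 0.226). ISG20 fell (9.89 ± 0.455 against 20.8 ± 2.55 CPM). Of the integrated stress and unfolded protein response genes, 2 rose and 1 fell of 20 (2 and 1 adjusted over the list alone, limma camera adjusted p = 0.87). MANF stood at 62.8 ± 8.29 against 29.6 ± 0.710 CPM and PDIA4 at 43.9 ± 11.1 against 82.5 ± 13.3 CPM. Of the tRNA splicing subunits, to which CLP1 binds, 2 rose and 0 fell of 9 (2 and 0 adjusted over the list alone, limma camera adjusted p = 0.226). TSEN34 stood at 64.9 ± 6.81 against 24.5 ± 3.81 CPM and TSEN2 at 37.1 ± 4.21 against 18.9 ± 1.87 CPM. Of the cytosolic ribosomal protein genes, 2 rose and 0 fell of 78 (0 and 0 adjusted over the list alone, limma camera adjusted p = 0.0973). RPL30 stood at 3213 ± 1779 against 1591 ± 306 CPM. Of the mitochondrially encoded mRNAs, 1 rose and 3 fell of 13 (1 and 3 adjusted over the list alone, limma camera adjusted p = 0.226). MT-ATP8 stood at 419 ± 70.0 against 971 ± 77.3 CPM. Of the cholesterol synthesis genes, 0 rose and 4 fell of 20 (1 and 6 adjusted over the list alone, limma camera adjusted p = 0.26). SQLE stood at 219.5 ± 42.0 against 468 ± 19.0 CPM and HMGCR at 24.6 ± 0.139 against 49.2 ± 1.09 CPM. Of the immediate early genes, 3 rose and 0 fell of 16 (3 and 0 adjusted over the list alone, limma camera adjusted p = 0.661). SRF stood at 35.7 ± 1.88 against 17.1 ± 1.74 CPM. The list's median log2 fold change was -0.036 and its mean 0.11. Of the stromal, endothelial and blood cell markers, 0 rose and 1 fell of 3 (0 and 2 adjusted over the list alone, limma camera adjusted p = 0.307). COL1A1 fell (19.3 ± 3.09 against 31.2 ± 4.32 CPM). Of the genes often studied for 3′ end choice, 2 rose and 1 fell of 17 (2 and 1 adjusted over the list alone, limma camera adjusted p = 0.916). PAK2 stood at 139 ± 39.5 against 45.1 ± 3.38 CPM. The count of 2394 became 1509 without siNT replicate 4, 1244 without siNT replicate 5 and 1069 without siCLP1 replicate 1, and 91 genes passed a test against a 2-fold change. For the 5 lists called here, limma's fry test of whether a list moved one way on balance gave adjusted p from 0.00374 to 0.105. Among them, only the estrogen response genes were not called by fry (limma fry adjusted p = 0.105). Unlike camera, fry also called the tRNA splicing subunits upwards (limma fry adjusted p = 0.0483).

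Set against each other, siPCF11 and siCLP1 differed in 524 genes, 185 higher and 339 lower in siPCF11, and 328 of them at least 2-fold. PCF11 itself was lower in siPCF11 (11.6 ± 0.107 against 35.6 ± 10.3 CPM, log2 fold change -1.61, edgeR adjusted p = 0.000833). CLP1 did not pass the test (9.02 ± 1.16 against 5.53 ± 1.96 CPM, log2 fold change 0.75, edgeR adjusted p = 0.249). FURIN stood at 10.2 ± 2.59 against 1.40 ± 1.01 CPM in siPCF11 and siCLP1 (log2 fold change 2.68, SE 0.41, edgeR adjusted p = 0.00081). KTN1, a kinesin-binding membrane protein, stood at 163 ± 2.40 against 43.9 ± 3.95 CPM, the transcriptional inhibitor ID2 at 37.4 ± 5.41 against 10.1 ± 0.268 CPM, CNNM4 at 17.7 ± 0.246 against 4.31 ± 0.962 CPM and ADM5 at 64.4 ± 4.51 against 17.5 ± 0.996 CPM. The small RNA genes SNORA11F (log2 fold change 2.05) and SCARNA21 (1.84) and the lincRNA AC145207.5 (2.16) were also higher in siPCF11. Lower in siPCF11 were NDUFAF3, an assembly factor of respiratory complex I (13.1 ± 2.11 against 62.1 ± 9.51 CPM), the proline synthesis enzyme PYCR3 (3.21 ± 1.58 against 15.4 ± 4.42 CPM), the lipid droplet protein PLIN5 (3.30 ± 2.51 against 14.6 ± 10.1 CPM) and the pseudogene CYP2T1P (1.75 ± 0.0516 against 12.02 ± 0.1253 CPM). The antisense RNAs A1BG-AS1 (log2 fold change -2.37), NOP14-AS1 (-2.22), TTC39A-AS1 (-2.16) and AP001469.2 (-2.10) were lower too, and because strand use in the counting is not given in the sources used here, their reads cannot be told from those of the partner genes. A list test was added here after the data were seen. It ranked cytosolic ribosomal protein genes towards siPCF11 (limma camera adjusted p = 2.98e-09, adjusted p = 0.935 with an estimated correlation), but 2 of 78 members passed alone and fry did not call the list (limma fry adjusted p = 0.558). It did the same for integrated stress and unfolded protein response genes (limma camera adjusted p = 0.0475, adjusted p = 0.775 with an estimated correlation, limma fry adjusted p = 0.284), of which 3 of 20 passed, including ATF4 (log2 fold change 1.07). Camera called none of the other lists in this comparison. The count of 524 became 344 without siPCF11 replicate 3, 120 without siPCF11 replicate 4, 277 without siCLP1 replicate 1 and 994 without siCLP1 replicate 3. It became 1144 with the letter of the sample titles as a block, 1043 with all 11 libraries in the fit, 859 without the low-count filter and 7 against a 2-fold change.

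Both knockdowns changed many genes in the same direction: 1339 genes were called in both comparisons with siNT, 722 higher and 617 lower, and 14 were called in opposite directions. Independent lists of these sizes would share 125 genes upwards and 123 downwards. In 20 simulations of unchanged groups against the same 3 siNT libraries at most 1 gene was called in both. No gene was changed there, so few calls could arise. That count therefore cannot show how far shared controls raise the overlap of real responses. Across the 14429 genes, which are not independent replicates, the log2 fold changes correlated with r = 0.676 (rho = 0.647), and simulated unchanged groups gave a mean r of 0.381. The covariance was 0.443, the simulated covariance averaged 0.0567, and the difference was 0.386. The 3 controls cannot be split into separate sets of 2 libraries, so part of the excess can come from the shared controls. The largest joint changes were in low transcripts. AOC3, an amine oxidase, stood at 7.48 ± 3.19, 0.900 ± 0.195 and 0.0342 ± 0.0593 CPM in siPCF11, siCLP1 and siNT, and the antisense RNA AL391834.1 at 2.39 ± 0.415, 1.25 ± 0.685 and 0.0354 ± 0.0613 CPM. SMIM31 (1.88 ± 0.0319 CPM in siNT), CCDC177 (1.84 ± 0.439 CPM), ATP13A5 (1.43 ± 0.810 CPM) and the mitochondrial carrier SLC25A18 (1.199 ± 0.410 CPM) had no reads in siPCF11. Their means in siCLP1 were at most 0.0865 CPM. The joint count became 824 without siNT replicate 4, 748 without siNT replicate 5, 837 without siPCF11 replicate 4 and 799 without siCLP1 replicate 1.

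**Figure D4:**
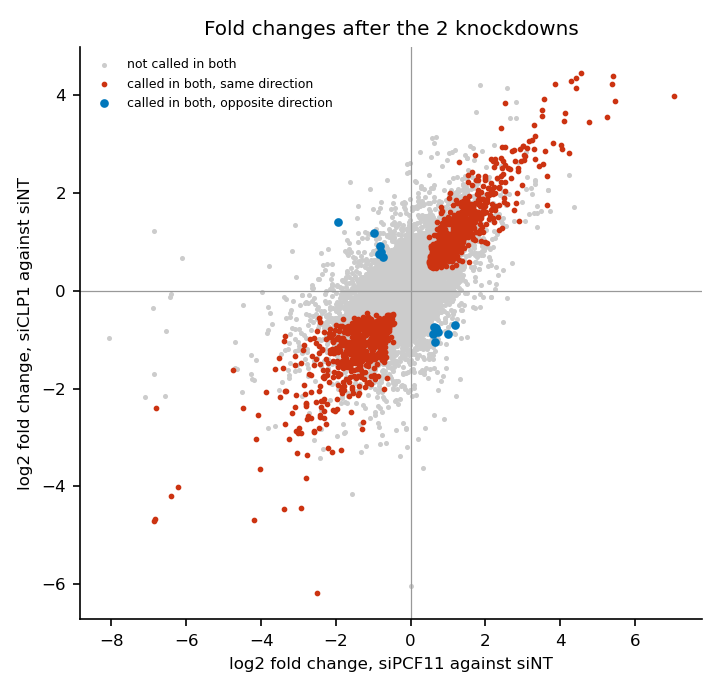
Log2 fold change of the 14429 tested genes after siPCF11 (horizontal) and siCLP1 (vertical), both against siNT. Red points are the 1339 genes called in both comparisons in the same direction, blue points the 14 called in opposite directions and grey points all others; both axes share the siNT libraries.

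The length of poly(A) tails was compared over genes with at least 20 tail-bearing reads in every library of the fit. A tail can be seen only as far as a read of 150 bases reaches beyond the transcript's 3′ end. Lengths and differences given here are therefore those of the sequenced part, and longer tails can be cut short. The median tail over genes was 49.4 ± 1.51 bases in MCF7 and 52.0 ± 0.610 bases in MDAMB231, and 48.1 ± 2.01 bases in siNT, 50.6 ± 1.02 bases in siPCF11 and 48.3 ± 0.658 bases in siCLP1. In the planned limma fits on unweighted values, without a block, no gene passed. An unadjusted limma p under 0.05 was seen in 1235 of 9540 genes between the lines. It was seen in 926 and 433 of 8262 genes in siPCF11 and siCLP1. Without any change a share near 0.05 would be expected, which the siCLP1 count barely exceeded. The median difference per gene was 2.40 bases between the lines, 2.14 bases for siPCF11 and 0.262 bases for siCLP1. A limma test weighted by tail-bearing reads, added after the data were seen, called 385 genes between the lines, 358 with longer and 27 with shorter tails in MDAMB231. After the median of each library was subtracted this split became 126 longer and 150 shorter. The weighted count became 856 without MCF7 replicate 1, 193 without MCF7 replicate 2, 60 without MDAMB231 replicate 1 and 132 without MDAMB231 replicate 2. The mitochondrial ribosomal RNAs had shorter tails in MDAMB231: MT-RNR1 20.1 ± 0.0153 against 30.8 ± 0.0222 bases (limma adjusted p = 1.98e-17) and MT-RNR2 26.2 ± 0.0276 against 31.9 ± 0.288 bases. Longer were BSG, a membrane glycoprotein (70.0 ± 0.708 against 57.7 ± 0.558 bases), the transketolase TKT (63.9 ± 0.186 against 52.6 ± 0.0311 bases), the glucosidase subunit GANAB (73.2 ± 1.07 against 58.4 ± 0.822 bases) and the respiratory chain subunit UQCR11 (58.1 ± 2.78 against 45.0 ± 1.90 bases). The largest differences were in UPK3BL1 (66.1 ± 0.583 against 35.4 ± 4.47 bases), WDR81 (88.2 ± 1.84 against 60.03 ± 11.3 bases), AKAP10 and OLFML2A among longer tails, and in AP5S1 (30.8 ± 9.66 against 54.7 ± 6.85 bases), MINK1 (45.2 ± 3.16 against 64.7 ± 0.0582 bases), ING2 and ELP5 among shorter.

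After siPCF11 the weighted test called 31 genes, 29 with longer and 2 with shorter tails, and in the siCLP1 libraries 16 genes, 13 longer and 3 shorter. With library medians subtracted, the split became 18 longer and 6 shorter in siPCF11, and 32 longer and 34 shorter in siCLP1. PTP4A2, a protein tyrosine phosphatase, had longer tails in both, 59.4 ± 0.838 against 39.9 ± 3.08 bases in siPCF11 and siNT (limma adjusted p = 0.000706) and 53.3 ± 2.84 bases in siCLP1 (limma adjusted p = 0.0131). GFRA1, a receptor of glial neurotrophic factor, was at 63.3 ± 1.05 against 48.0 ± 2.43 bases in siPCF11 and 58.0 ± 3.13 bases in siCLP1, and the joint entry of TMEM189-UBE2V1 and UBE2V1 was the third gene called in both. Both tests used the same siNT libraries, and no number expected without change was computed, so the 3 joint calls do not show a shared effect on tails. In siPCF11 the mitochondrial tRNA genes MT-TM (36.0 ± 2.38 against 26.3 ± 1.65 bases) and MT-TF (37.0 ± 2.03 against 27.0 ± 0.876 bases), the membrane GTPase ATL3 (62.4 ± 3.11 against 43.6 ± 4.05 bases), CDS2 (66.3 ± 0.190 against 44.6 ± 2.19 bases), FAM206A and TTC3 had longer tails. DCAF11 (39.8 ± 0.285 against 56.1 ± 1.33 bases) and METRN (56.7 ± 1.58 against 70.9 ± 1.60 bases) had shorter ones. In siCLP1 the xylosyltransferase XYLT2 (62.7 ± 13.3 against 43.3 ± 3.75 bases), NUP210 (76.5 ± 1.45 against 57.2 ± 6.36 bases), FAM204A, POLDIP3 (54.4 ± 18.0 against 40.2 ± 2.28 bases) and MRFAP1 had longer tails. C19orf25 (46.6 ± 0.0383 against 64.1 ± 4.31 bases), MAP7 (24.8 ± 10.4 against 36.3 ± 2.75 bases) and G6PD (47.8 ± 2.58 against 52.6 ± 2.87 bases) had shorter ones. The tail means given for single genes, here and between the lines, are unweighted. The weighted test used other differences, such as 25.5 bases for XYLT2, 20.8 for POLDIP3 and -16.4 for MAP7. By their SDs, the siCLP1 libraries differed widely in these genes. PCF11 mRNA itself had tails of 61.8 ± 3.44 bases in siPCF11 and 47.6 ± 2.13 bases in siNT, which did not pass the unweighted limma test (adjusted p = 0.347). The 31 genes became 4 without siNT replicate 4, 4 without siNT replicate 5, 8 without siPCF11 replicate 3 and 0 without siPCF11 replicate 4. The 16 genes became 6 without siNT replicate 3, 10 without siPCF11 replicate 3, 244 without siCLP1 replicate 3, and 0 without siNT replicate 4, siNT replicate 5 or siCLP1 replicate 1, and 66 with library medians subtracted. Poly(A) site usage was not analysed here, because the tables used hold a single value per gene and library.

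**Figure D5:**
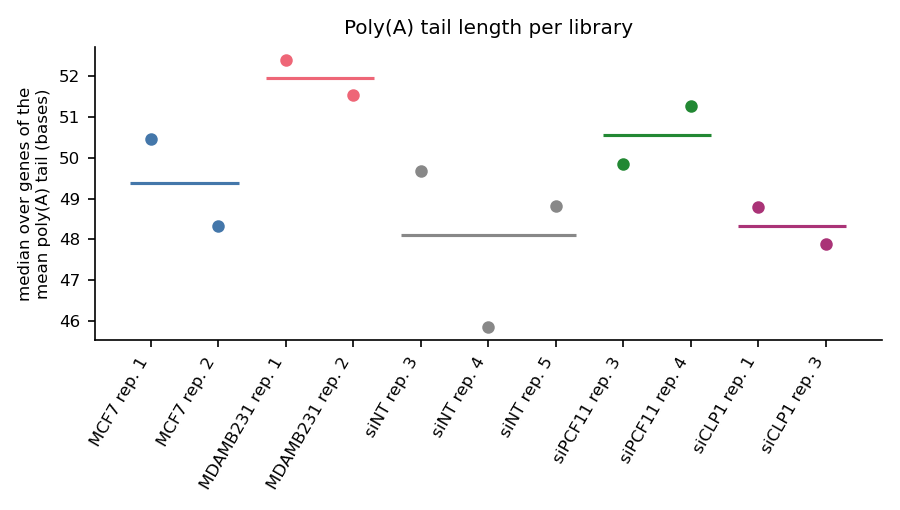
Median over genes of the mean poly(A) tail length, in bases, in each of the 11 libraries (points) with group means (horizontal lines); the axis does not start at 0. The siNT libraries lie between 45.9 and 49.7 bases, a span wider than the differences between the means of the compared groups.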

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

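Tail-bearing reads alone and all weighted tail tests were chosen after seeing the data; the other alternatives were planned, and the planned tests of poly(A) site usage with their alternatives were not run, since the tables hold no separate 3′ ends. Of 3013 recomputed values, covering 246 results of a gene in a comparison, 4 reversed direction, of which 0 were called in either fit: CLP1 in siCLP1 against siNT (-0.33 as reported, 0.091 with tail-bearing reads alone, -0.71 to 0.031 without each library, highest without siCLP1 replicate 1), and CLIP1 in siCLP1 against siNT (-0.36 as reported, -0.92 to 0.022, highest without siCLP1 replicate 3) and in the direct comparison (-0.12 as reported, -0.50 to 0.44, highest without siCLP1 replicate 1), all log2 fold changes. Of values that kept their direction, 79 of 21 genes lost their call in siCLP1 and 63 of 22 genes in siPCF11. In the direct comparison 12 values of 5 genes lost it, and between the lines 6 values of 3 genes. A call was gained in 3 values of 1 gene in siPCF11 and in 2 values of 1 gene in siCLP1. Some of these fits left 1 library in a group. Counts of changed genes with DESeq2, with its size factors and with tail-bearing reads alone stayed within 1.5 times those reported in all 4 comparisons. Against a 2-fold change (a stricter question) 6227, 282, 91 and 7 genes were called for MDAMB231, siPCF11, siCLP1 and the direct comparison of the knockdowns. With an estimated correlation 0 lists were called for MDAMB231, 0 for siPCF11 and 0 for siCLP1. The title letter as a block gave 9 lists for siPCF11 instead of 7, adding the integrated stress and unfolded protein response (up, limma camera adjusted p = 0.0442) and the mitochondrially encoded mRNAs (down, adjusted p = 0.0122), and 5 for siCLP1 as reported; leaving out each library gave 7 to 10 and 5 to 7. With the title letter as a block, fry called the estrogen response genes in siPCF11 (limma fry adjusted p = 0.00804) and in siCLP1 (0.00512). In siPCF11 it still did not call the ribosomal protein genes (0.091) or the genes often studied for 3′ end choice (0.0677). The direct comparison gave 859 genes without the low-count filter, 1144 with the title letter as a block and 1043 with all 11 libraries in a fit. The labels give no meaning to a shared number or letter: with the number as a block 11631 and 3942 genes were called for MDAMB231 and siPCF11, and with the letter as a block 3802 for siPCF11, 3035 for siCLP1 and 1761 in the overlap. Across genes, deviations from the group means correlated with r = -0.021 for MCF7 with MDAMB231 replicate 1, and with 0.377 for siNT with siPCF11 replicate 3 and 0.316 for replicate 4, which share number and letter. They correlated with 0.203 for siNT replicate 3 and 0.179 for siPCF11 replicate 3 with siCLP1 replicate 1 (letter only). With siCLP1 replicate 3 (number only), siNT replicate 3 gave -0.203. In a group of 2 libraries the deviations are exact opposites. The values of 0.377 and 0.316 are therefore not independent of each other, and -0.203 restates 0.203. Leaving out each library in turn, where a group left with 1 library is assumed to vary like the others, gave 11284 to 11555 genes for MDAMB231 and 1431 to 3474 for siPCF11 (1951 without siNT replicate 5, 1877 without siPCF11 replicate 3, 1431 without siPCF11 replicate 4). It gave 1069 to 2353 for siCLP1 (1509 without siNT replicate 4, 1244 without siNT replicate 5, 1069 without siCLP1 replicate 1), and 120 to 994 for the direct comparison (344 without siPCF11 replicate 3, 120 without siPCF11 replicate 4, 277 without siCLP1 replicate 1, 994 without siCLP1 replicate 3). The overlap ran from 748 to 1175 (824 without siNT replicate 4, 748 without siNT replicate 5, 837 without siPCF11 replicate 4, 799 without siCLP1 replicate 1). Unweighted tail tests called 0 genes; for siPCF11 a minimum of 50 reads gave 2, the number block 66 (54 longer, 12 shorter), the letter block 0, and leaving out each library 0 to 1 (1 without siPCF11 replicate 4). Weighted tail tests gave 385 for MDAMB231, 31 for siPCF11 and 16 for siCLP1 (66 with library medians subtracted, 32 longer and 34 shorter). Without each library these ran from 60 to 856 for MDAMB231 (856 without MCF7 replicate 1, 193 without MCF7 replicate 2, 60 without MDAMB231 replicate 1, 132 without MDAMB231 replicate 2), from 0 to 43 for siPCF11 (4 without siNT replicate 4, 4 without siNT replicate 5, 8 without siPCF11 replicate 3, 0 without siPCF11 replicate 4) and from 0 to 244 for siCLP1 (6 without siNT replicate 3, 0 without siNT replicate 4, 0 without siNT replicate 5, 10 without siPCF11 replicate 3, 0 without siCLP1 replicate 1, 244 without siCLP1 replicate 3). Apart from the stricter fold threshold, the cause was not tested. At 5082772 to 15561054 reads, low transcripts such as CLP1 carry wide intervals.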

Other observations

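Tests of gene classes, tail shares, MDAMB231 transcripts in MCF7 replicate 2, GC content and the knockdowns' shared response were chosen after seeing the results. Predictions for abundance, neighbouring genes and siNT replicate 3 were set before their tests, but no analysis of gene length was part of the plan. Of 548 antisense RNAs tested, 44 rose and 93 fell in siPCF11 (limma camera adjusted p = 0.027, adjusted p = 0.289 with an estimated correlation), while 55 rose and 24 fell in siCLP1, where the shift did not pass (limma camera adjusted p = 0.0938, adjusted p = 0.374 with an estimated correlation). In the direct comparison 0 were higher and 26 lower in siPCF11 (limma camera adjusted p = 1.17e-06, adjusted p = 0.0613 with an estimated correlation). Of 448 lincRNAs, 1 was higher and 14 were lower in siPCF11 than in siCLP1 (limma camera adjusted p = 0.0243, adjusted p = 0.0613 with an estimated correlation). Of 105 sense intronic RNAs, 16 rose and 1 fell in siCLP1 (limma camera adjusted p = 4.04e-05, adjusted p = 0.374 with an estimated correlation), and 14 rose and 4 fell in siPCF11.

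Genes whose reads rarely carried a tail rose more often than they fell. Of 464 genes with a tail in under 10% of reads, 50 rose and 6 fell in siPCF11 (median log2 fold change 0.39) and 67 rose and 9 fell in siCLP1 (median 0.52). Among the other 13965 genes, 1374 rose and 1571 fell in siPCF11, and 1199 rose and 1119 fell in siCLP1. Small nuclear RNAs were among the classes that moved up: of 53, 5 rose and 1 fell in siPCF11 (limma camera adjusted p = 0.0144, adjusted p = 0.289 with an estimated correlation), and 6 rose and 2 fell in siCLP1 (limma camera adjusted p = 0.00358, adjusted p = 0.374 with an estimated correlation).

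MCF7 replicate 2 held low levels of transcripts typical of MDAMB231. Over 41 genes above 50 CPM in MDAMB231 and under 0.2% of that level in siNT, the median level was 1.09% of MDAMB231 in MCF7 replicate 2 and 0.282% in MCF7 replicate 1. The median ratio of 3.16 between the replicates (quartiles 1.59 to 5.78) argues against reads misassigned alike across libraries as the whole of it. Such reads stay open for the level in MCF7 replicate 1. In the MDAMB231 libraries, 35 MCF7-type genes stood at near-equal medians of 0.486% and 0.435% of the MCF7 level. These genes were chosen for a low share in MDAMB231, so their medians are low by selection and cannot decide this. MDAMB231 material or reads mixed into replicate 2 stay open: the excess there should follow the MDAMB231 level across genes, and the Spearman correlation of 0.625 had an interval too wide to decide (95% interval 0.368 to 0.794). No biological explanation was tested.

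Shorter genes fell more often after siPCF11: of protein-coding genes in 5 classes of genomic length, 21.9% fell in the shortest, and 6.46% in the longest (odds ratio 4.05, 95% interval 3.33 to 4.94), with an odds ratio of 1.78 (1.46 to 2.18) in siCLP1. As the whole cause, GC content (odds ratio 2.73 within 5 GC classes, 2.18 to 3.41), low abundance (4.44 within 5 abundance classes, 3.63 to 5.42) and siNT replicate 3 (3.57 without it, 2.91 to 4.39) are argued against. A neighbouring expressed gene may contribute: within length classes, genes with a tested gene inside 5 kb fell more often (odds ratio 1.45, 1.28 to 1.65). With a neighbour inside 1 kb the odds ratio was no larger (1.39, 1.23 to 1.56). GC content was not held fixed in these 2 tests. Among single libraries the contrast of short with long genes was largest in siPCF11 replicate 4 (-0.21 on the log2 scale) and siNT replicate 3 (0.20), and it was -0.039 in siPCF11 replicate 3. The intervals of the odds ratios count genes as independent and leave out this spread between libraries. No odds ratio was computed without siPCF11 replicate 4. A difference between libraries therefore stays open beside PCF11 depletion, which is a hypothesis here.

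The knockdowns shared a response although CLP1 mRNA was not shown to be lower. Shared siNT libraries as its whole cause are argued against by a covariance of log2 fold changes of 0.443, where simulated unchanged groups reached at most 0.0595. An innate response to more siRNA stays open: per library, the mean log2 CPM of 19 interferon-stimulated genes differed from siNT by -0.55 in siPCF11 (95% interval -2.42 to 1.32) and by -0.32 in siCLP1 (-2.19 to 1.55), too wide to decide. The larger siRNA volume cannot be told apart from the knockdowns, since 0 non-targeting libraries received it. Loss of CLP1 itself may have contributed and cannot be told apart either: the log2 fold change of CLP1 was -0.33 (95% interval -0.99 to 0.33), 0.091 with tail-bearing reads alone, 0.031 without siCLP1 replicate 1 and -0.71 without siCLP1 replicate 3.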
